A study of Arabidopsis thaliana with 24 samples.

How the data were processed

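Small RNA of Arabidopsis thaliana was measured in 24 libraries: 16 from leaves of WT, rns1 and rns2 (unwounded, 0 h, or 3 h after wounding) and 8 from WT or rns2 leaf extract with or without added tRNA. Per the labels the plants were 4 weeks old and the libraries were made with a small RNA kit after size selection on a gel. The deposited files hold each distinct sequence of a library with its read count, a whole number without normalisation. Per the submitters' processing notes the genome build was TAIR10. The aligner, the trimmer and the length filter are not given in the sources used here. Adapters had been removed before deposit: leaf files hold sequences of 13 to 40 nt and extract files of 2 to 142 nt, so the 2 sets were not compared by length beyond 40 nt. No library here is labelled as the control of tRNA without extract that the study design mentions, so fragments already in the added tRNA cannot be told from those made in the extract.

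Distinct sequences (tags) of 15 to 60 nt were matched without mismatches to TAIR10 with a search written in Python 3.11.15 (NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, numba 0.67.0, figures with matplotlib 3.10.9). Each tag was counted by its reads, so all numbers and shares of tags below are of reads. A plain search of 19101 sequences of 1 library in the tRNA sequences gave the same answer as the list of tRNA stretches for all 19101. It checked only that list, made from the same tRNA sequences, and neither the search itself nor the other kinds of RNA. A tag was given to the first kind it matched, in the order tRNA, rRNA, miRNA, miRNA precursor, other annotated short RNA, mRNA in the sense direction, other annotated RNA and genome. The tRNA reference held 684 genes with 260 distinct mature sequences, with and without the 3′ CCA, in 96 families of genome and anticodon: 49 nuclear, 30 chloroplast and 17 mitochondrial. Nuclear 25S rRNA is not annotated in the reference, so 3600 nt downstream of 5.8S were taken. A feature is a family with a fragment class. 5′ fragments start at position 1 or 2, and in nuclear and mitochondrial His also at the G added before position 1. They are 5′ short (end at 30 or before), 5′-half (31 to 40) or 5′ long (later). 3′ fragments reach the 3′ end and are 3′-half (start at 31 to 42) or 3′ short (later start), and other fragments are internal or full length. Tags that match more than 1 family count in class shares and were left out of features: 7.49 ± 0.709% of tRNA tags in unwounded rns2 leaves up to 13.9 ± 0.160% in wounded WT leaves, and 22.7 ± 1.97% in WT extract and 35.9 ± 1.21% with added tRNA.

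Totals per library were 2477880 to 16071157 reads in leaf and 14472448 to 32379311 in extract, and 82.2% to 94.2% of tags of 15 to 60 nt matched. At these depths 3 counts, the floor used for items with 0 counts, come to 0.115 to 1.85 CPM per leaf library and 0.153 to 0.428 per extract library after TMM scaling. Replicates were grouped by genotype and treatment. Libraries of 1 group differ by more than counting error (chi-square per degree of freedom 6.58 to 117), so no library is a copy of another of its group. Copies between groups were not looked for. Replicate numbers pair WT and rns1 leaf libraries: deviations from the group means correlated in 3 of 3 pairs for WT wounding (0.21 to 0.51), rns1 wounding (0.26 to 0.44), rns1 against WT before wounding (0.48 to 0.63) and after it (0.42 to 0.66). The pairing comes from the data, since the labels give only numbers. Two-sided tests used edgeR 4.0.16 (quasi-likelihood, glmQLFit and glmQLFTest) in R 4.3.3 with TMM scaling on all features and filterByExpr, 1 fit of 16 leaf libraries and 1 of 8 extract libraries. These tested 339 tRNA features, 109 miRNA families and 3743 genes in leaves and 399 tRNA features in extract. Adjusted p-values are Benjamini-Hochberg values over the features of a kind, with 0.05 as the threshold. TMM factors were 1.79 to 1.87 in unwounded WT, 1.95 to 1.97 in unwounded rns1, 1.09 to 1.37 in wounded WT, 1.03 to 1.17 in wounded rns1 and 0.286 to 0.312 in rns2 leaves, and 0.658 to 1.53 in extract, so folds between rns2 and WT depend on the scaling. Shares of matched tags were compared by two-sided exact permutation of the difference in means.

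Lists fixed before the data were examined were tested with camera (preset correlation 0.01, and with an estimated correlation) and fry, which asks whether a list moves on balance one way, on voom values (limma 3.58.1), adjusted over lists. There were 31 tRNA lists (6 fragment classes, 3 genomes and 22 amino acids), miRNA lists for copper, phosphate, sulphate, auxin, development and jasmonate, and the small RNA pathway, and gene lists for jasmonate and wounding, RNase T2, phosphate starvation, salicylate and pathogen, clock, and markers of guard cell, phloem companion cell, epidermis and mesophyll photosynthesis. Lists with too few measured members were not tested, and full-length fragments had no feature past the filter. Features named in the text follow a rule: RNS1 and RNS2 first, the 5 largest rises and falls per tRNA comparison with adjusted p under 0.05, no overlap of groups and a mean of 10 CPM or more (interactions without the overlap condition), the 10 most abundant features in leaf and in extract, the 10 largest rises and falls of miRNA and mRNA with a mean of 10 CPM or more and no overlap within any genotype, and list members. Where the rule gives more names than the text needs, the first of them are given.

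Alternatives were scaling to library totals, TMM on miRNA alone, no low-count filter (10 tags in total), tags of 18 to 60 nt, 1 mismatch to tRNA, a replicate block, the compared groups alone, DESeq2 1.42.0, each library left out, and for shares all tags in the file or the ratio to miRNA as denominator. Families by amino acid, tags of 13 to 60 nt, tags of 15 to 40 nt, miRNA and mRNA without the rns2 leaf libraries a block in the list test and a block with rns2 leaf numbers 2 and 3 were added later. The edgeR test was run on simulated counts with the spread and the scaling factors of the real libraries. In them 60 tRNA features, 30 miRNA families or 200 genes changed, with rises and falls in equal number, and libraries were not paired. The simulation does not test the scaling, the low-count filter or the pairing. In WT wounding 15%, 60% and 100% of features changed 1.5-fold, 2-fold and 4-fold were recovered, in rns2 wounding 10%, 45% and 75%, in rns1 against WT 15%, 45% and 95%, in WT extract 10%, 15% and 90%, in miRNA 20%, 70% and 100% and in mRNA 19.4%, 53.7% and 89.4%. Of unchanged features at most 0.358% were called. Tags under 15 nt were left out because tags so short can match many places. Of all reads, 13 to 14 nt tags were 5.06% to 9.44% of WT leaf libraries and 14.9% to 18.5% of rns2 leaf libraries.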

Results

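Short RNA was sequenced from leaves of Arabidopsis thaliana in 24 libraries, with fragments cut from tRNA (tsRNAs) as the main interest. 16 libraries came from wild-type (WT), rns1 and rns2 leaves that were unwounded (0 h) or taken 3 h after wounding, with 3 libraries per group for WT and rns1 and 2 per group for rns2. RNS1 and RNS2 encode RNases of the T2 family: RNS1 is a secreted enzyme made after wounding, and RNS2 is a vacuolar enzyme that turns over ribosomal RNA. The other 8 libraries came from WT or rns2 leaf extract incubated in vitro with or without added tRNA, with 2 libraries per group. Totals ranged from 2477880 reads (rns1 wounded replicate 2) to 16071157 reads (rns1 unwounded replicate 2) in leaf libraries and from 14472448 to 32379311 reads in extract libraries. Of the tags of 15 to 60 nt, each counted by its reads here and below, 82.2% to 94.2% matched the reference. Unwounded leaves were taken only at 0 h. Effects called wounding here and below therefore cannot be told from those of 3 h of elapsed time or of time of day. The labels do not state whether replicates are separate plants, so the p-values measure the spread between these libraries, which may be technical. Changes given as a value ± SE are log2 folds from edgeR, and normalised read counts (CPM after TMM scaling) and percentages ± SD. A 5′ short fragment ends at tRNA position 30 or before, a 5′-half fragment at 31 to 40 and a 5′ long fragment later. A 3′-half fragment reaches the tRNA's 3′ end from a start at 31 to 42, and a 3′ short fragment from a later start.

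RNS1 (AT2G02990, TAIR10 chromosome 2, 873506 to 874886) left fragments after wounding in WT leaves, 17, 15 and 8 per library or 2.61 ± 0.588 CPM without TMM scaling (n = 3), and 0 in each of the 3 unwounded WT libraries. Against a floor of 3 counts per library, which allows up to 0.444 to 0.759 CPM in those 3 libraries, RNS1 fragments were at least 4.73-fold higher after wounding. In rns1 leaves both groups were at or under the floor, with 1 fragment over 3 libraries each. Wounded rns2 leaves held 4 and 6 RNS1 fragments and unwounded ones 1 and 0, a ratio of 14.5 with a 95% counting interval of 2.06 to 629.6. The 8 extract libraries held 0 RNS1 fragments, which allows up to 0.112 to 0.486 CPM per library. RNS2 (AT2G39780, TAIR10 chromosome 2, 16591117 to 16593775) left 4 fragments in unwounded and 6 in wounded WT libraries, 1 and 4 in rns1 and 1 and 1 in rns2. In extract libraries it left 8 in WT, 7 in WT with added tRNA, 0 in rns2 and 1 in rns2 with added tRNA. RNS2 fragments were too few to compare groups. Floors and intervals cover counting error only, and the CPM of this paragraph are without TMM scaling.

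The share of matched tags that came from tRNA answers whether wounding or loss of an RNase changes the amount of tRNA fragments relative to other short RNA. In WT leaves it was 8.20 ± 1.13% before and 40.9 ± 6.39% after wounding (n = 3 each), 4.99-fold higher with no overlap. In rns1 it was 8.05 ± 0.728% and 49.1 ± 3.72% (n = 3 each), 6.10-fold higher. In rns2 it was already 28.6 ± 0.472% before wounding and 34.03 ± 1.11% after it (n = 2 each), 1.19-fold higher. Unwounded rns2 leaves thus held 3.49 times the tRNA share of unwounded WT leaves, while nuclear tRNA fragments per miRNA tag were 71.9-fold higher there. With 3 against 3 libraries the two-sided exact permutation test gave p = 0.1, the smallest it can give, for both WT and rns1 wounding. With 2 against 3 the smallest is 0.1 as well and with 2 against 2 it is 0.333, so no share could pass 0.05. The exact p was 0.9 for rns1 against WT before wounding, 0.2 for rns1 against WT after it and 0.3 for rns2 against WT after it. Taken by replicate number, the wounded rns1 share lay above that of WT in 3 of 3 pairs, by 5.99 to 11.3 points, and the unwounded one in 1 of 3. An exact permutation test by pairs (signs changed within pairs), chosen after these values were seen, gave p = 0.25 after wounding, the smallest it can give with 3 pairs, and 0.75 before it.

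**Figure D1:**
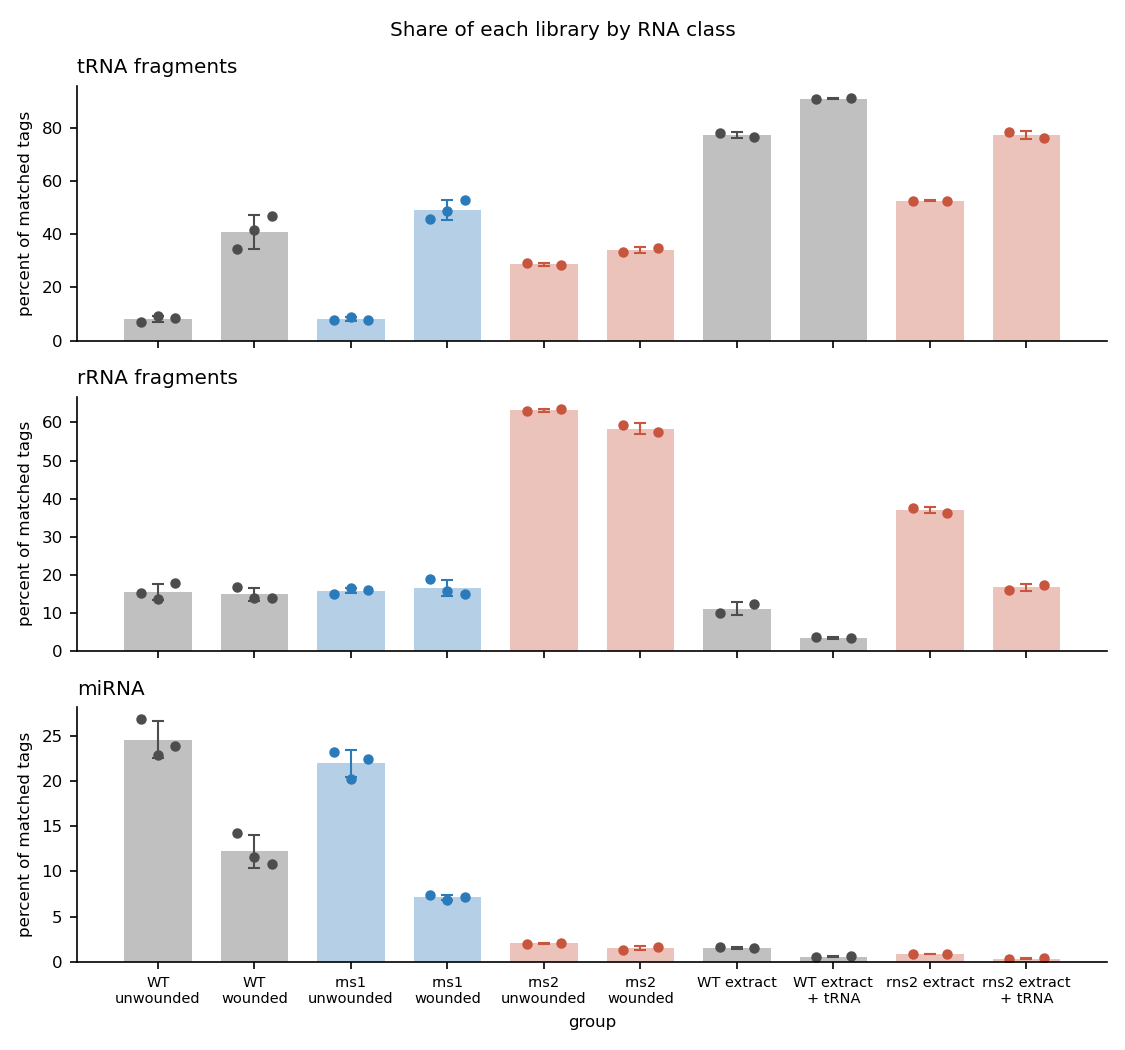
Percentage of matched tags (vertical axis) from each kind of RNA in each library of the 10 groups, with bars for group means ± SD and points for libraries. In WT the tRNA share was 8.20 ± 1.13% before and 40.9 ± 6.39% after wounding, while rns2 leaves held 63.2 ± 0.413% rRNA before wounding.

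The higher WT share lay in 5′ fragments of nuclear tRNA. 5′ short fragments were 2.70 ± 0.526% of tags before and 20.5 ± 3.28% after wounding, and 5′-half fragments 2.75 ± 0.560% and 16.9 ± 2.88% (n = 3 each). 3′ short fragments stayed within their spread, 1.80 ± 0.218% and 1.96 ± 0.246% (exact p = 0.5). Nuclear tRNA gave 4.74 ± 0.648% and 31.9 ± 5.77% of tags, chloroplast tRNA 3.06 ± 0.449% and 7.05 ± 0.482%, and mitochondrial tRNA 0.0651 ± 0.0533% and 1.27 ± 0.242%, 19.6-fold higher. Nuclear Ala 5′ short fragments alone reached 10.2 ± 1.80% of tags in wounded WT leaves, from 0.538 ± 0.163%. In rns2 leaves rRNA fragments filled most of the library, 63.2 ± 0.413% before wounding against 15.6 ± 2.07% in WT. Nuclear 25S gave 39.8 ± 0.559% there and nuclear 18S 17.9 ± 0.333%, while miRNA held 2.02 ± 0.0640% against 24.6 ± 2.03% in WT. Chloroplast tRNA held 0.267 ± 0.0240% in unwounded rns2 leaves, 0.0872 times the WT share, and per miRNA tag it was 1.05 times that in WT.

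**Figure D2:**
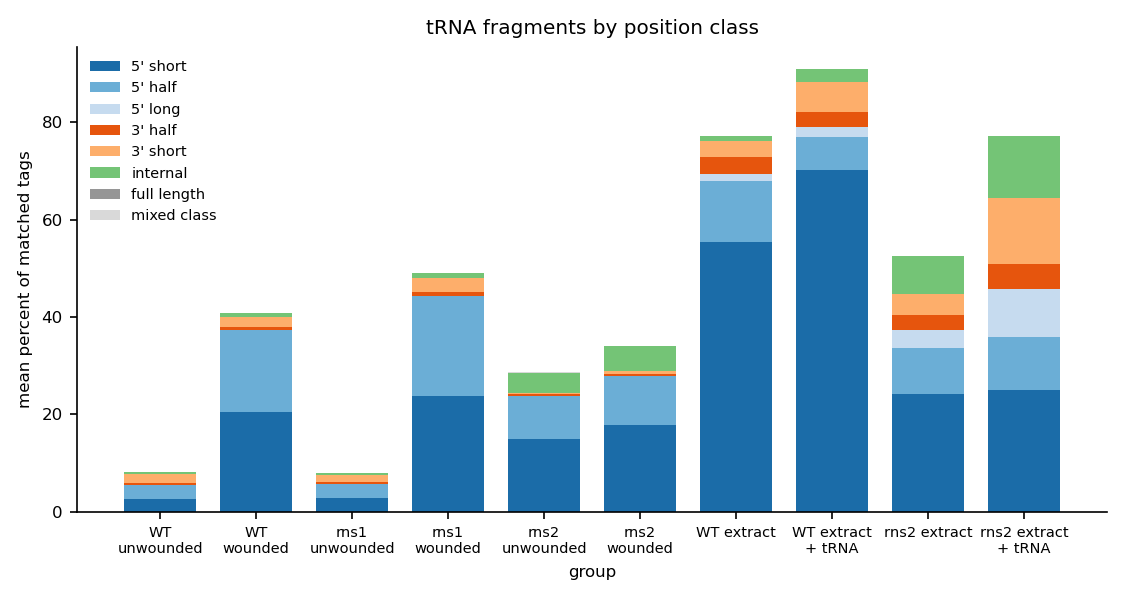
Stacked mean percentage of matched tags (vertical axis) in each tRNA fragment class for the 10 groups. 5′ short and 5′-half fragments make up most of the tRNA share in leaves, and in WT extract with added tRNA 5′ short fragments reach 70.1 ± 0.207%.

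WT wounding asks which tRNA fragments accumulate in 3 h. The largest rise in WT was chloroplast Arg(ACG) 5′ short, 6.85 ± 0.53 (adjusted p = 2.9e-09), from 23.7 ± 17.5 to 2758 ± 1205 CPM (n = 3 each), with GGGCTTGTAGCTCAGAGGA as 83.7% of its tags. Nuclear Cys(GCA) 5′-half rose by 6.35 ± 0.41, His(GTG) 5′-half by 5.56 ± 0.47 and Arg(TCT) 5′ short by 5.498 ± 0.51. Nuclear Ala(CGC) 5′ short rose by 5.31 ± 0.34, from 550.3 ± 207 to 21776 ± 5202 CPM. The 16-nt tag GGGGGTGTAGCTCATA, positions 1 to 16 of tRNAs such as AT1G64420 (chromosome 1, 23933137 to 23933209), made up 94.2% of it, so with tags of 18 nt or more its fold was -0.17. Averaged over all 16 leaf libraries, in which the rns2 libraries weigh most, the most abundant features were nuclear Asp(GTC) 5′-half and 5′ short and Ala(AGC) 5′ short; in wounded WT leaves Asp(GTC) 5′ short, at 8035 ± 3523 CPM, lay below Gly(TCC) 5′-half, at 23100.4 ± 4101. Asp(GTC) 5′-half (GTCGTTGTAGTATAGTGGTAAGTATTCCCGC, tRNAs such as AT1G03515, chromosome 1, 877648 to 877719) rose from 2611 ± 837 to 48576 ± 20677 CPM, 4.22 ± 0.41. Ala(AGC) 5′ short (GGGGATGTAGCTCAGA, AT1G06610, chromosome 1, 2025356 to 2025428) rose by 4.57 ± 0.35, Gly(TCC) 5′-half by 4.37 ± 0.30 and Glu(TTC) 5′-half by 4.55 ± 0.40. The falls were smaller and mostly 3′ short: nuclear Leu(TAA) at -1.23 ± 0.21, Leu(AAG) at -0.85 ± 0.27, Leu(CAG) at -0.79 ± 0.24 and Arg(CCG) at -0.75 ± 0.23, beside chloroplast Leu(TAA) 5′-half at -0.84 ± 0.23. Single libraries decide 3 of these falls: Leu(AAG) lost its call without WT unwounded replicate 2 (adjusted p = 0.0505), Leu(CAG) without WT wounded replicate 2 (adjusted p = 0.0641) and Arg(CCG) without WT unwounded replicate 3 (adjusted p = 0.0585).

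Of 339 features tested in WT, 243 rose and 21 fell with wounding. The groups did not overlap for 258 of all 339 (chance gives 10% for 3 against 3). They did not overlap for 248 of the 264 called, which were chosen by the same libraries. The median of all features was 1.88. Scaling to library totals shifted it by -0.59 and gave 211 rises and 59 falls, and scaling on miRNA alone shifted it by 0.15. Of the 6 fragment classes, 5′ short rose most often, 70 of 72 with 0 falls (70 and 0 adjusted over the list alone), above the other features (camera adjusted p = 3.87e-08, adjusted p = 0.804 with an estimated correlation). 3′ short features lay below the rest (adjusted p = 4.42e-28), which held with an estimated correlation (0.0312): 12 of 73 rose and 18 fell (12 and 13 adjusted over the list alone), with median -0.19 and mean 0.06. 5′ long features, 5 in number with 1 fall, also lay below (adjusted p = 0.00757, adjusted p = 0.804 with an estimated correlation). Leaf files end at 40 nt, so 5′ long features in leaves hold only 40-nt tags that start at position 2. Leaf 3′-half fragments over 40 nt are missing for the same reason. 47 of 58 5′-half, 45 of 54 3′-half and 69 of 77 internal features rose. By compartment 143 of 197 nuclear features rose and 18 fell, 96 of 134 chloroplast features rose and 3 fell, and 4 of 8 mitochondrial features rose.

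**Figure D3:**
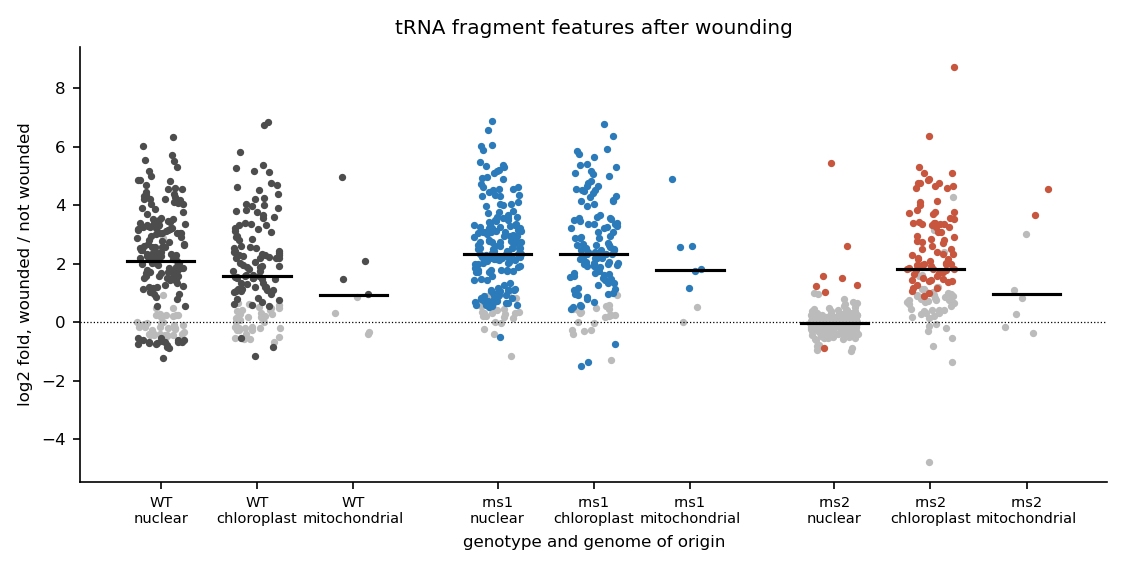
Log2 fold after wounding (vertical axis) of each tested tRNA feature, by genotype and genome of origin (horizontal axis), with called features coloured and lines at the medians. Nuclear features lie well above 0 in WT and rns1 and close to 0 in rns2, where chloroplast features stay above 0 with a median of 1.82.

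In rns1 leaves wounding raised 5′ fragments as well. Nuclear Cys(GCA) 5′-half rose by 6.89 ± 0.42 (adjusted p = 1.3e-10; 23.1 ± 6.27 to 2752 ± 515 CPM, n = 3 each), chloroplast Arg(ACG) 5′ short by 6.78 ± 0.53, nuclear Arg(ACG) 5′ short by 6.57 ± 0.43, chloroplast Ile(CAT) 3′-half by 6.37 ± 0.50 and nuclear Gln(CTG) 5′ short by 6.07 ± 0.30. Among abundant features Asp(GTC) 5′-half rose by 4.36 ± 0.41 and Ala(AGC) 5′ short by 4.64 ± 0.35. Among the 4 falls were chloroplast Arg(TCT) 5′-half, -1.49 ± 0.27, chloroplast Leu(TAA) 5′-half, -0.76 ± 0.23, and nuclear Leu(TAA) 3′ short, -0.51 ± 0.21, the last not called without rns1 unwounded replicate 2 or 3, rns1 wounded replicate 2 or 3 (adjusted p = 0.0708 to 0.224). 288 features rose and 4 fell, with no overlap for 289 of all 339 features and 282 of the 292 called. The median was 2.32, shifted by -0.81 with library totals and by 0.49 with miRNA scaling. 71 of 72 5′ short features rose (71 adjusted over the list alone; camera adjusted p = 5.99e-07). 3′ short features lay below the other features (8.61e-08) although 50 of 73 rose and 1 fell (48 and 1 adjusted over the list alone). Their median was 0.81 and mean 0.96, and library totals put the median at 0.00. 5′ long features, again only 40-nt tags that start at position 2, lay below too (1.46e-04; 2 of 5 rose and 1 fell). Their median was 0.17, which library totals turned to -0.66. None of the 3 calls held with an estimated correlation (adjusted p = 0.462 for each). With the replicate block, Ala features lay below the rest too (adjusted p = 0.0293, against 0.0582 without it; 8 of 17 rose, 7 adjusted over the list alone).

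Whether the response to wounding differs between rns1 and WT was tested by the interaction. The wounding fold was higher in rns1 for 48 features and lower for 1, of 339. The largest differences were nuclear Cys(GCA) internal, 2.11 ± 0.47 (adjusted p = 0.0122), chloroplast Met(CAT) 5′ short, 2.09 ± 0.65, nuclear Gly(GCC) 5′ short, 1.92 ± 0.44, chloroplast Asn(GTT) internal, 1.81 ± 0.33, and nuclear Tyr(GTA) 3′ short, 1.77 ± 0.37. Chloroplast Arg(TCT) 5′-half fell more in rns1, with a difference of -1.28 ± 0.38. Met(CAT) was not called without any 1 of WT unwounded replicate 2, WT wounded replicate 1 or 2, rns1 unwounded replicate 1 or 2, rns1 wounded replicate 1 or 2 or 3 (adjusted p = 0.0597 to 0.241), Gly(GCC) without WT wounded replicate 2 (adjusted p = 0.0584) and Arg(TCT) without any 1 of WT unwounded replicate 1 or 2, WT wounded replicate 2 or 3, rns1 unwounded replicate 1 or 2, rns1 wounded replicate 1 or 3 (adjusted p = 0.0502 to 0.0890). 3′ short features made up 25 of the 48 (40 of 73 adjusted over the list alone; camera adjusted p = 3.51e-08), and 7 of 15 Gln features had a higher fold (8 adjusted over the list alone; 0.0400). 5′-half (adjusted p = 0.00438; by edgeR 1 of 58 higher and 1 lower, 0 and 0 adjusted over the list alone) and 3′-half features (0.00916; by edgeR 0 of 54 called) lay below the rest while their medians, 0.28 and 0.06, and means were above 0, and library totals turned the 3′-half median to -0.14. No list call held with an estimated correlation (adjusted p = 0.992). Asp(GTC) 5′-half, 0.14 ± 0.51, and Ala(AGC) 5′ short, 0.07 ± 0.43, did not pass. The median was 0.55, shifted by -0.21 with library totals, which left 14 and 2 calls, and by 0.34 with miRNA scaling, which gave 121 and 0. With the replicate block the fold was higher for 83 features and lower for 3, Asp(GTC) 5′ short among the former (1.01, adjusted p = 0.0287), DESeq2 called 88 in all, and a fit to the compared groups alone 23. The count of 49 was 31 without WT unwounded replicate 2, 24 without WT unwounded replicate 3, 8 without WT wounded replicate 2, 22 without rns1 unwounded replicate 1, 31 without rns1 unwounded replicate 2, 17 without rns1 wounded replicate 1 and 25 without rns1 wounded replicate 3.

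In rns2 leaves wounding raised chloroplast fragments and few nuclear ones. Chloroplast Ile(CAT) 3′-half went from 1 read over 2 libraries to 328, 99.0 ± 20.8 CPM (n = 2), a ratio of 454 with a 95% counting interval of 80.9 to 17985. Chloroplast Ser(TGA) 5′-half rose by 5.30 ± 0.40 (adjusted p = 1.16e-08; 5.29 ± 1.60 to 203 ± 26.6 CPM, n = 2 each), Pro(TGG) 5′-half by 5.11 ± 0.72, His(GTG) 5′-half by 5.11 ± 0.48 and fMet(CAT) 3′-half by 4.89 ± 0.63, all chloroplast. The 1 fall was nuclear Pro(CGG) 5′-half, -0.90 ± 0.31 (adjusted p = 0.0386), not called without rns2 unwounded replicate 1 (adjusted p = 0.103) or rns2 wounded replicate 1 (adjusted p = 0.156). The abundant nuclear features were not called: Asp(GTC) 5′-half -0.06 ± 0.44, Ala(AGC) 5′ short 0.16 ± 0.37 and Gly(TCC) 5′-half -0.18 ± 0.32. 93 of 339 features rose and 1 fell. The groups did not overlap for 210 of all 339 (chance gives 33.3% for 2 against 2), among them all 94 called. 84 of 134 chloroplast features rose (94 adjusted over the list alone) with a median of 1.82, above the other features (camera adjusted p = 3.56e-33), and 7 of 197 nuclear features rose and 1 fell (2 and 0 adjusted over the list alone), below them (1.51e-33). Both calls held with an estimated correlation (adjusted p = 0.00475). The nuclear median was -0.03 and mean 0.02, and the median turned to 0.03 with library totals and 0.40 with miRNA scaling. fMet features lay above the rest (0.00484; 4 of 5 rose), which held with an estimated correlation (0.0499). His (0.0169; 7 of 14 rose) and Ser (0.0169; 14 of 24) did not hold, with adjusted p = 0.903 and adjusted p = 0.407 with an estimated correlation. The median of all features, 0.20, shifted by 0.43 with miRNA scaling.

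The interaction tests the rns2 difference itself. The wounding fold was lower in rns2 than in WT for 145 features and higher for 18. The largest negative differences were nuclear: Cys(GCA) 5′-half -5.93 ± 0.56 (adjusted p = 3.93e-07), Arg(CCG) 5′ short -5.66 ± 0.51, Arg(TCT) 5′ short -5.48 ± 0.71, Arg(ACG) 5′ short -5.45 ± 0.57 and Ala(CGC) 5′ short -5.02 ± 0.48. For Gly(TCC) 5′-half it was -4.55 ± 0.44 and for Asp(GTC) 5′-half -4.28 ± 0.59. For chloroplast His(GTG) 5′-half the fold was higher in rns2 by 3.81 ± 0.55, for Val(TAC) 5′-half by 2.88 ± 0.39, His(GTG) internal by 2.64 ± 0.36, Asp(GTC) 5′-half by 2.27 ± 0.48 and Phe(GAA) 5′-half by 2.13 ± 0.56, the last not called without rns2 unwounded replicate 2 (adjusted p = 0.0932). Of 197 nuclear features 130 had a lower fold and 1 a higher (132 and 1 adjusted over the list alone; camera adjusted p = 1.75e-16), while of 134 chloroplast features 16 had a higher and 14 a lower (13 and 10 adjusted over the list alone; 2.47e-15). The fold was lower for 52 of 72 5′ short features and higher for 1 (54 and 1 adjusted over the list alone; 2.88e-07), and 3′ short features lay above the rest (1.51e-12; 4 of 73 higher, 0 adjusted over the list alone). With an estimated correlation none held: adjusted p = 0.167 for both compartments, 0.755 for 5′ short and 0.174 for 3′ short. The median was -0.62. Library totals shifted it by 0.61 and gave 118 features with a lower fold and 82 with a higher, and miRNA scaling shifted it by 0.26.

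rns1 against WT in unwounded leaves asks what RNS1 does without wounding. 21 features were lower in rns1 and 1 higher, all with no overlap. Over all 339 features the groups did not overlap for 83, where chance gives 10%. Nuclear Gly(TCC) 3′ short was lower in rns1, at -1.02 ± 0.22 (adjusted p = 0.0381; 164 ± 21.6 CPM in WT and 81.0 ± 3.38 in rns1, n = 3 each), Arg(ACG) 3′ short at -0.96 ± 0.22, Trp(CCA) 3′ short at -0.90 ± 0.24, Ser(AGA) 5′ short at -0.90 ± 0.19 and Ile(TAT) 3′ short at -0.90 ± 0.25. Asp(GTC) 5′-half, 0.31 ± 0.36, and Ala(AGC) 5′ short, 0.16 ± 0.30, did not pass. 3′ short features lay below the rest (camera adjusted p = 1.9e-15; 17 of 73 lower, 32 adjusted over the list alone). 3′-half (6.25e-07; 1 of 54 higher) and 5′-half features (9.84e-04; 0 of 58 called) lay above. With an estimated correlation these gave adjusted p = 0.161, 0.9997 and 0.912. The count rests on the spread between few libraries. With library totals edgeR called 0 (66 at unadjusted p under 0.05 with TMM scaling), with miRNA scaling 4, without the low-count filter 4, with tags of 18 to 60 nt 0, with the compared groups alone 0, with DESeq2 43, and with the replicate block 52 (9 higher and 43 lower). It was 0 without WT unwounded replicate 1 or 3 and without rns1 unwounded replicate 1, 2 or 3.

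After wounding, rns1 leaves held more of several fragments than WT leaves. Chloroplast fMet(CAT) 3′-half was higher by 2.30 ± 0.40 (adjusted p = 0.00345; 33.5 ± 19.4 to 163 ± 13.8 CPM, n = 3 each), nuclear Arg(ACG) 5′ short by 1.74 ± 0.35, chloroplast Met(CAT) 5′ short by 1.73 ± 0.41, nuclear Gln(CTG) 5′ short by 1.67 ± 0.25 and Val(AAC) 3′-half by 1.58 ± 0.42. The 3 lower features were chloroplast Arg(TCT) 5′-half, -1.48 ± 0.27, nuclear Ile(AAT) 5′ short, -0.92 ± 0.31, and Thr(TGT) 5′ short, -0.63 ± 0.20. Met(CAT) was not called without WT wounded replicate 2 (adjusted p = 0.0604), Val(AAC) without WT wounded replicate 2 (adjusted p = 0.0836) or rns1 wounded replicate 3 (adjusted p = 0.0602), Ile(AAT) without any 1 of WT wounded replicate 2 or 3, rns1 wounded replicate 1 or 2 (adjusted p = 0.0942 to 0.159) and Thr(TGT) without any 1 of WT wounded replicate 1 or 2 or 3, rns1 wounded replicate 1 or 2 (adjusted p = 0.0735 to 0.159). 55 of 339 features were higher, and the groups did not overlap for 105 of all 339 and 51 of the 58 called. 6 of 15 Gln features were higher (7 adjusted over the list alone; camera adjusted p = 0.0354, adjusted p = 0.993 with an estimated correlation). The median was 0.40, shifted by -0.14 with library totals (48 higher, 10 lower) and by 0.32 with miRNA scaling (145 higher, 1 lower). The replicate block gave 85 higher and 8 lower, Glu(CTC) 5′ short among the former (0.79, adjusted p = 0.0366), DESeq2 91 calls and the compared groups alone 30. The count was 13 without WT wounded replicate 2, 29 without rns1 wounded replicate 3 and 38 without rns1 wounded replicate 1.

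rns2 against WT in unwounded leaves asks which fragments accumulate when RNS2 is lost. Nuclear Arg(CCT) internal was higher by 8.19 ± 0.35 (adjusted p = 1.71e-12), 5462 ± 82.1 CPM (n = 2) against 18.7 ± 3.93 in WT (n = 3), followed by Met(CAT) 3′-half, 7.996 ± 0.69, Thr(AGT) internal, 7.97 ± 0.40, Ala(TGC) internal, 7.89 ± 0.47, and Cys(GCA) 3′-half, 7.72 ± 0.50. Asp(GTC) 5′-half was higher by 5.82 ± 0.45 and Ala(AGC) 5′ short by 6.80 ± 0.40. Chloroplast fragments were lower: Cys(GCA) 3′-half at -2.501 ± 0.32 and 3′ short at -2.497 ± 0.30, Gly(TCC) 3′ short at -2.26 ± 0.37, Lys(TTT) 3′ short at -2.07 ± 0.33 and Thr(TGT) 5′-half at -1.94 ± 0.32. 164 features were higher and 62 lower. The groups did not overlap for 264 of all 339 (chance gives 20% for 2 against 3) and 225 of the 226 called. The median of all features was 0.73 and depended on the scaling: library totals shifted it by -2.60 and gave 110 higher and 194 lower, and miRNA scaling shifted it by 0.53 and gave 184 and 19. Nuclear features lay above chloroplast ones: 153 of 197 nuclear features were higher and 10 lower (153 and 11 adjusted over the list alone; camera adjusted p = 6.48e-29) and 51 of 134 chloroplast features were lower and 9 higher (48 and 8 adjusted over the list alone; 1.28e-27), and both calls held with an estimated correlation (adjusted p = 0.0107). Internal features lay above (6.96e-04; 52 of 77 higher, 2 lower) and 3′ short below (2.19e-11; 28 of 73 lower and 8 higher, 24 and 6 adjusted over the list alone), with adjusted p = 0.951 and 0.152 with an estimated correlation. The 3′ short median was -0.55 and turned to 0.01 with miRNA scaling, and the 5′ short and 5′-half medians, 2.02 and 0.64, turned to -0.63 and -1.83 with library totals.

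After wounding the largest rns2 excesses were in internal fragments. Nuclear Ala(TGC) internal was higher than in WT by 6.44 ± 0.46 (adjusted p = 1.51e-09), Glu(TTC) internal by 5.90 ± 0.44, Asp(GTC) internal by 5.83 ± 0.38, Pro(AGG) internal by 5.46 ± 0.31 and Glu(CTC) internal by 5.42 ± 0.33. Asp(GTC) internal, mostly GTTGTAGTATAGTGGTAAGTATTCCC from positions 4 to 29, stood at 55774 ± 6679 CPM in rns2 (n = 2) and 983 ± 317 in WT (n = 3). Chloroplast 5′ short fragments were lower: Thr(TGT) at -4.79 ± 0.38, Pro(TGG) at -3.16 ± 0.30, Arg(ACG) at -2.97 ± 0.52, Ile(CAT) at -2.42 ± 0.34 and Glu(TTC) at -2.28 ± 0.30. 141 features were higher and 43 lower. The groups did not overlap for 235 of all 339, among them all 184 called. The median was 0.41, shifted by -1.99 with library totals (54 higher, 210 lower) and by 0.84 with miRNA scaling (212 and 12). Asp(GTC) 5′-half was higher by 1.54 ± 0.39, Gly(TCC) 5′-half by 1.62 ± 0.29 and Glu(TTC) 5′-half by 1.43 ± 0.38, and library totals turned these to -0.43, -0.38 and -0.55. Asp(GTC) was not called without rns2 wounded replicate 2 (adjusted p = 0.125) and Glu(TTC) without rns2 wounded replicate 2 (adjusted p = 0.105). Gly(TCC) 5′ short, 1.97 ± 0.27, turned to -0.02. His(GTG) 5′-half and Ala(CGC) 5′ short, not called at 0.83 ± 0.43 and 0.24 ± 0.32, turned to -1.16 and -1.76 under library totals. Nuclear features lay above (camera adjusted p = 1.96e-13; 118 of 197 higher and 7 lower, 119 and 7 adjusted over the list alone) and chloroplast ones below (35 of 134 lower and 20 higher). Scaling shifts all features nearly alike: library totals turned the nuclear median from 1.40 to -0.60 and miRNA scaling the chloroplast median from -0.31 to 0.51. Internal (5.68e-07; 51 of 77 higher, 1 lower) and 3′-half features (0.00123; 38 of 54 higher, 3 lower) lay above the rest, the internal median turning from 1.61 to -0.39 with library totals. 5′ short (0.00351; 24 higher and 23 lower, 26 and 24 adjusted over the list alone), 3′ short (0.00123; 10 and 10, 9 and 9 adjusted over the list alone) and Leu features (0.0292; 5 and 5 of 28) lay below. Their medians were -0.25, 0.02 and -0.15 and their means 0.08, -0.04 and 0.00. miRNA scaling turned the 5′ short and Leu medians to 0.57 and 0.68, and library totals the 3′ short median to -2.01. With an estimated correlation both compartments gave adjusted p = 0.259 and the other 5 lists 0.934.

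Where 5′ fragments end asks where tRNA was cleaved. In wounded WT leaves 29.1 ± 0.275% of tags from 5′ fragments ended at position 16, in the D loop, against 18.5 ± 3.93% before wounding (n = 3 each). Without the tags of nuclear Ala the share at position 16 was 9.27 ± 0.659% after and 15.2 ± 3.12% before wounding, so it was higher after wounding only with them. Ends at positions 15 to 22 were 39.0 ± 6.29% before and 48.0 ± 0.841% after wounding with all tags, and 33.01 ± 6.34% and 28.5 ± 1.25% without nuclear Ala (30.9 ± 0.336% and 26.3 ± 5.90% in rns1, n = 3 each). In rns2 leaves the shares ending at position 16 were 21.4 ± 0.729% and 23.2 ± 2.72% (n = 2 each). In WT extract 50.1 ± 6.55% ended there, and 72.0 ± 1.77% with added tRNA. In rns2 extract the values were 32.1 ± 4.29% and 17.7 ± 1.35% (n = 2 each). Without nuclear Ala tags they were 16.0 ± 0.258% and 13.3 ± 2.55% in WT extract and 19.7 ± 4.26% and 10.4 ± 0.511% in rns2 extract. Ends at positions 23 to 30, between the D loop and the anticodon loop, made up 28.0 ± 0.809% and 29.6 ± 1.35% in unwounded and wounded rns2 leaves, 10.5 ± 1.18% and 6.87 ± 0.161% in WT and 10.2 ± 0.785% and 11.7 ± 0.730% in rns1. Cleavage between A and T accounted for 8.46 ± 2.75% of 5′ fragment ends in unwounded WT leaves, 31.8 ± 0.920% in wounded ones, 50.4 ± 7.57% in WT extract and 17.8 ± 1.17% in rns2 extract. In rns2 leaves cleavage between C and C was more frequent, 26.9 ± 0.0915% before and 23.3 ± 1.72% after wounding, against 10.6 ± 0.749% and 11.8 ± 0.919% in WT. Main tags of nuclear Ala(AGC) and Ala(CGC) 5′ short also end in A at position 16, and that of Asp(GTC) 5′-half ends in C. Shares by bases were not taken without these families, so a preference for bases cannot be told from the sites of abundant families. With 2 or 3 libraries per group these shares could not pass an exact permutation test at 0.05.

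**Figure D4:**
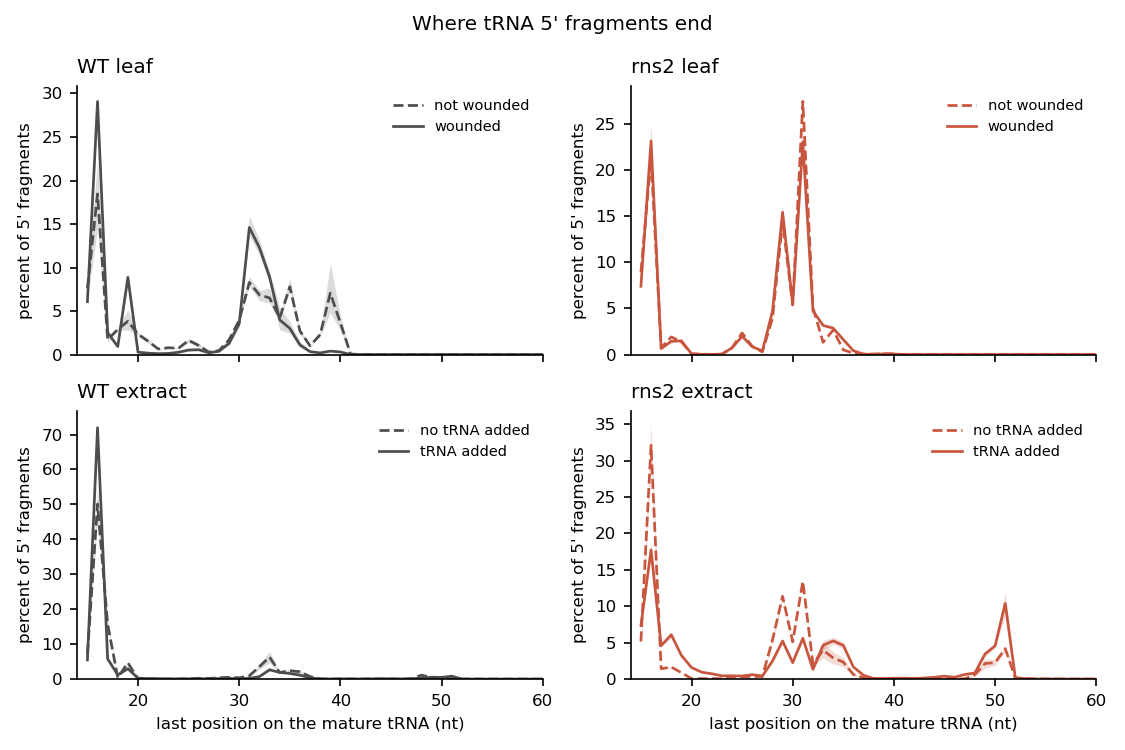
Percentage of tags from 5′ tRNA fragments (vertical axis, own scale in each panel) that end at each tRNA position (horizontal axis), by group, with leaf tags limited to 40 nt. Position 16 holds 72.0 ± 1.77% in WT extract with added tRNA and 17.7 ± 1.35% in rns2 extract with added tRNA.

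Adding tRNA to WT leaf extract asks which fragments appear when an extract meets more tRNA. No library of added tRNA without extract is labelled here, so fragments already present in the added tRNA cannot be told from cleavage in the extract, here and in rns2 extract. tRNA made up 77.3 ± 1.02% of tags without and 91.0 ± 0.156% with added tRNA (n = 2 each), and nuclear Ala 5′ short fragments 32.9 ± 5.69% and 57.1 ± 1.41%. Ala(AGC) 5′ short, the highest on average over the 8 extract libraries, rose by 1.23 ± 0.32 (adjusted p = 0.00422), from 97561 ± 23938 to 228503 ± 17653 CPM, and Ala(CGC) 5′ short by 1.01 ± 0.34. Ala(AGC) was not called without WT extract plus tRNA replicate 1 (adjusted p = 0.153), and Ala(CGC) without any 1 of WT extract replicate 2, WT extract plus tRNA replicate 1 or 2 (adjusted p = 0.0654 to 0.349). The largest rises were 5′ long fragments of nuclear Gln(CTG), 7.28 ± 0.77, chloroplast Val(TAC), 7.26 ± 0.61, nuclear Asp(GTC), 6.71 ± 0.45, and His(GTG), 6.31 ± 0.45, and chloroplast Gly(TCC) 5′ short, 6.65 ± 0.49. The largest falls were chloroplast Ser(TGA) 5′ long, -2.59 ± 0.47, Gln(TTG) 5′ short, -2.15 ± 0.35, nuclear Arg(CCG) 5′ short, -1.93 ± 0.32, chloroplast Gly(GCC) 3′ short, -1.84 ± 0.31, and Ser(TGA) 5′-half, -1.69 ± 0.28. Chloroplast Pro(TGG) 5′ short fell too, -1.66 ± 0.38, but with tags of 18 nt or more its fold was 1.80, its main tag being 17 nt. Of 399 features 237 rose and 38 fell, with no overlap for 274 of these 275, and 166 were called without WT extract plus tRNA replicate 1. Over all 399 features the groups did not overlap for 344. The median was 1.27, shifted by -0.73 with library totals (165 rises, 79 falls) and by 1.16 with miRNA scaling (333 and 3). Gly(TCC) 5′-half, -0.31 ± 0.29 and not called, turned to 0.77 with miRNA scaling. Internal features (56 of 77 rose, 2 fell; camera adjusted p = 0.0433) and Val features (20 of 25 rose, 21 adjusted over the list alone) lay above the rest, and Arg (15 rose, 7 fell) and Ser (15 and 7) below, all at adjusted p = 0.0433. 5′-half (19 rose and 12 fell, 19 and 10 adjusted over the list alone) and Pro features (2 and 7, 2 and 5 adjusted over the list alone) lay below at 6.7e-04. The medians of 5′-half, Arg and Ser were above 0 (0.28, 0.59 and 0.73), although the test put them below the rest, and turned to -0.37, -0.15 and -0.01 with library totals. The Pro median, -0.27, turned to 0.85 with miRNA scaling. No call held with an estimated correlation (adjusted p = 0.957).

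The same addition to rns2 extract asks which fragments appear without RNS2. tRNA made up 52.5 ± 0.124% and 77.3 ± 1.62% of tags (n = 2 each), but 5′ short fragments 24.2 ± 3.64% and 25.03 ± 1.37%, while 3′ short fragments went from 4.26 ± 0.996% to 13.6 ± 0.397% and 5′ long ones from 3.60 ± 0.711% to 9.83 ± 1.47%. Chloroplast Gly(TCC) 5′ short rose by 9.43 ± 0.55 (adjusted p = 4.86e-09; 19.4 ± 8.03 to 13356 ± 4417 CPM), nuclear Tyr(GTA) 3′ short by 8.40 ± 0.40, Gln(CTG) 3′ short by 8.23 ± 0.41, chloroplast Gly(TCC) 3′ short by 8.18 ± 0.40 and chloroplast Trp(CCA) 5′ long by 7.71 ± 0.45. Ala(AGC) 5′ short, 0.34 ± 0.32, and Ala(CGC) 5′ short, 0.18 ± 0.34, were not called. The falls were chloroplast Ser(GGA) 3′-half, -5.31 ± 0.63, Ser(GCT) 3′-half, -4.24 ± 0.60, Ser(TGA) 5′ long, -2.52 ± 0.47, Leu(TAA) 3′-half, -1.64 ± 0.41, and nuclear Arg(CCG) internal, -1.48 ± 0.33, the last turning to 0.62 with tags of 18 nt or more. Leu(TAA) was not called without rns2 extract plus tRNA replicate 2 (adjusted p = 0.115), and Arg(CCG) without rns2 extract plus tRNA replicate 2 (adjusted p = 0.148). Glu(CTC) 5′ short, -0.10 ± 0.42 and not called, was 1.70 with such tags and 0.75 with miRNA scaling, and Gly(TCC) 5′-half, -0.03 ± 0.29, was 0.80 with miRNA scaling. 303 of 399 features rose and 9 fell, none with overlap, and the groups did not overlap for 353 of all 399. The median was 2.04, shifted by -0.57 with library totals and by 0.80 with miRNA scaling. 70 of 74 3′ short features rose, above the rest (camera adjusted p = 2.12e-06). 5′-half (0.0274; 36 rose and 2 fell, 35 and 2 adjusted over the list alone), 3′-half (0.0483; 51 and 3) and Ser features (4.11e-08; 13 and 6 of 36, 12 and 6 adjusted over the list alone) lay below the rest with medians above 0 (1.24, 1.52 and 0.43), the Ser median turning to -0.18 with library totals. With an estimated correlation the 3′ short, 5′-half and 3′-half calls gave adjusted p = 0.987 and Ser 0.920.

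rns2 against WT extract asks which cleavage depends on RNS2 when no tRNA is added. Chloroplast 5′ short fragments were lower in rns2: Arg(ACG) at -5.71 ± 0.45, Pro(TGG) at -5.49 ± 0.45, Thr(TGT) at -5.31 ± 0.47 and Trp(CCA) at -4.52 ± 0.46, as was nuclear Arg(TCG) 5′ short at -5.10 ± 0.37. Pro(TGG) stood at 1441 ± 838 CPM in rns2 and 64864 ± 651 in WT (n = 2 each; adjusted p = 2.76e-07). Nuclear Ala(AGC) 5′ short was lower at -2.06 ± 0.33 and Ala(CGC) 5′ short at -3.42 ± 0.38. These features consist mainly of tags of 16 to 19 nt, and with tags of 18 nt or more Pro(TGG), Thr(TGT) and Trp(CCA) gave 0.08, 0.00 and 0.08, and fMet(CAT) 5′ short, -4.44 ± 0.41, gave 1.99. Tags left out as too short were unequal. Those of 13 to 14 nt were 26.1% and 21.5% of reads in rns2 and 6.94% and 6.91% in WT extract. Those under 13 nt were 24.4% and 21.7% against 7.27% and 7.67%. With tags of 13 to 60 nt no single result turned direction, and tags under 13 nt were not tested. Higher in rns2 were chloroplast Leu(TAA) 5′ long, 6.61 ± 0.47, nuclear Asp(GTC) internal, 6.28 ± 0.40, chloroplast Tyr(GTA) 3′-half, 5.73 ± 0.58, nuclear Pro(AGG) internal, 5.27 ± 0.36, and Gly(TCC) internal, 5.16 ± 0.40. 139 of 399 features were higher and 121 lower. The median was 0.22, shifted by 0.17 with library totals and by 0.99 with miRNA scaling, which gave 215 higher and 57 lower. Internal features lay above the rest (camera adjusted p = 2.32e-09; 52 of 77 higher, 3 lower) and 3′ short below (4.74e-07; 46 of 74 lower and 4 higher, 47 and 4 adjusted over the list alone), with adjusted p = 0.968 for both with an estimated correlation.

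With tRNA added, several 5′ short fragments stayed lower in rns2 than in WT. Ala(CGC) 5′ short was lower at -4.26 ± 0.39 (adjusted p = 1.27e-06; 8238 ± 333 against 157635 ± 21118 CPM, n = 2 each), Arg(TCG) at -3.45 ± 0.34, Ala(AGC) at -2.95 ± 0.34, chloroplast Pro(TGG) at -2.76 ± 0.40 and fMet(CAT) at -2.74 ± 0.38, all 5′ short. Chloroplast Trp(CCA) 5′ short, lower without added tRNA, did not pass here (0.32 ± 0.39, looked up after the other values were seen). With tags of 18 nt or more, which leave out their main tags of 16 and 17 nt, Ala(CGC), Ala(AGC), Pro(TGG) and fMet(CAT) gave 2.52, 0.88, 1.80 and 1.29. Nuclear Asp(GTC) internal was higher by 5.56 ± 0.38, Pro(CGG) internal by 4.81 ± 0.41, chloroplast Ala(TGC) 3′ short by 4.59 ± 0.39, and Pro(TGG) and Arg(CCG) internal by 4.52 ± 0.34 and 4.37 ± 0.37. 253 features were higher and 31 lower, none with overlap, and the groups did not overlap for 354 of all 399. The median was 1.24, shifted by 0.33 with library totals and by 0.63 with miRNA scaling. Internal features lay above the rest (camera adjusted p = 1.24e-08; 73 of 77 higher, 1 lower), and nuclear ones above (157 of 225 higher, 11 lower) and chloroplast (91 of 163 and 19, 89 and 17 adjusted over the list alone), 5′ short (44 and 16) and Arg (13 and 6) below, each at 0.0281. The medians of these last 3 were above 0 (1.05, 1.16 and 0.63). No call held with an estimated correlation (adjusted p = 0.963).

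Whether added tRNA acts differently in rns2 and WT extract was tested by the interaction. The fold was higher in rns2 for 146 features and lower for 26, of 399. For chloroplast Ala(TGC) 3′ short it was higher by 5.79 ± 0.51 (adjusted p = 7.32e-06), nuclear Cys(GCA) 5′ long by 5.23 ± 0.54, chloroplast Trp(CCA) 5′ short by 4.84 ± 0.59, Arg(ACG) 3′ short by 4.32 ± 0.48 and nuclear Lys(TTT) 3′ short by 4.30 ± 0.47. Chloroplast Tyr(GTA) 3′-half, -3.54 ± 0.69, His(GTG) 5′-half, -3.04 ± 0.47, and Leu(TAA) 5′-half, -2.92 ± 0.45, rose less in rns2, while Ser(GGA) 3′-half, -3.95 ± 0.77, and Ser(GCT) 3′-half, -3.26 ± 0.77, fell more, Ser(GCT) not being called without rns2 extract replicate 2 (adjusted p = 0.0509). Ala(AGC) and Ala(CGC) 5′ short, -0.89 ± 0.45 and -0.84 ± 0.48, did not pass, and gave 1.83 and 3.47 with tags of 18 nt or more, while fMet(CAT) 5′ short went from 1.70 ± 0.50 to -0.71. Of 74 3′ short features 61 had a higher fold and 2 a lower (64 and 2 adjusted over the list alone; camera adjusted p = 2.92e-10, adjusted p = 0.984 with an estimated correlation). The median was 0.85, shifted by 0.16 with library totals and by -0.34 with miRNA scaling, which gave 102 with a higher fold and 38 with a lower.

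The wounding effect on miRNA families, averaged over the 3 genotypes, asks which other short RNAs respond (8 wounded and 8 unwounded libraries). 2 of 109 families rose and 34 fell, and 15 of the 36 did not overlap within any genotype. miR1888 rose by 0.85 ± 0.17 (adjusted p = 4.7e-04). miR5020 fell, at -1.36 ± 0.16, miR166 and miR162, which act on leaf polarity genes and on DCL1, at -1.099 ± 0.18 and -1.03 ± 0.17, miR775 at -1.02 ± 0.11, miR399, which acts in phosphate signalling, at -0.97 ± 0.13, miR391 at -0.93 ± 0.12, miR159 at -0.93 ± 0.15, miR319 at -0.91 ± 0.12, miR164 at -0.76 ± 0.11 and miR472 at -0.74 ± 0.12. miR393, which targets auxin receptors, rose by 0.82 ± 0.14 (adjusted p = 1.27e-04), in an auxin list where miR167 and miR390 fell, -0.57 ± 0.13 and -0.51 ± 0.10, and which as a whole did not pass (camera adjusted p = 0.639; median -0.21, turning to 0.15 with miRNA scaling). 7 of 8 families of the development and jasmonate list fell (7 adjusted over the list alone), with miR165 at -1.45 ± 0.25 and miR172 not called at 0.32 ± 0.25, below the other families (0.00678, adjusted p = 0.257 with an estimated correlation). miR156 was not called without any 1 of WT wounded replicate 2, rns1 unwounded replicate 1, rns1 wounded replicate 2 (adjusted p = 0.0562 to 0.0644). All 4 families of the small RNA pathway list fell, miR168 at -0.58 ± 0.13 (0.0158, adjusted p = 0.182 with an estimated correlation). 2 of 4 copper families fell (0.666), with miR398 at -0.35 ± 0.12 turning to 0.01 with miRNA scaling and not called without any 1 of WT unwounded replicate 1 or 2, WT wounded replicate 1 or 2, rns1 unwounded replicate 1 or 2, rns1 wounded replicate 1 or 2 (adjusted p = 0.0520 to 0.118), and miR408 at -0.37 ± 0.13 not called without any 1 of WT unwounded replicate 2 or 3, WT wounded replicate 2 or 3, rns1 unwounded replicate 2 or 3, rns1 wounded replicate 2 (adjusted p = 0.0605 to 0.110). 1 of 2 phosphate families fell (0.581). miR395, alone in the sulphate list, fell, at -0.60 ± 0.22, but not without any 1 of WT unwounded replicate 3, WT wounded replicate 2, rns1 unwounded replicate 2 or 3, rns1 wounded replicate 1 or 2, rns2 unwounded replicate 2, rns2 wounded replicate 1 (adjusted p = 0.0529 to 0.128). The median of all families was -0.39, shifted by -0.43 with library totals (1 rise, 61 falls) and by 0.35 with miRNA scaling (9 rises, 11 falls), so the number of falls depends on the scaling.

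Sense fragments of mRNA in the same libraries ask which genes' fragments changed. A change in fragments can come from the level of an mRNA or from its breakdown, which were not told apart. Folds of genes here and in the next paragraph are folds of such fragments. 589 of 3743 genes rose and 469 fell, and 360 of the 1058 did not overlap within any genotype. The direction of the bulk depends on the scaling: the median was -0.18, library totals shifted it by -0.43 and gave 319 rises and 1442 falls, and miRNA scaling shifted it by 0.35 and gave 899 and 49. Among genes with a mean of 10 CPM or more the largest rises were AT3G59710 (chromosome 3, 22054667 to 22057156), 4.38 ± 0.20 (adjusted p = 2.19e-51), AT2G20410 (chromosome 2, 8802091 to 8804422), 3.61 ± 0.12, and AT1G72645, 3.00 ± 0.17. Next came chloroplast photosynthesis genes: psbA, for a core protein of photosystem II, 2.77 ± 0.07, from 768 to 5315 CPM, psaA 2.66 ± 0.08, atpE 2.45 ± 0.11, psaB 2.41 ± 0.08 and psbC 2.39 ± 0.08, with rps14 2.28 ± 0.12 and cemA 2.19 ± 0.14. The largest falls were between -0.93 ± 0.17 (AT3G49070) and -0.74 ± 0.12 (AT4G08485). Between them lay AT5G35160, AT5G28040, the sucrose transporter gene SUC6 at -0.82 ± 0.17, AT3G49230, AT1G15010, AT1G34440, AT5G27882 and AT5G44270.

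Fragments of genes of the jasmonate and wounding list rose, for 11 of 12 genes measured (12 adjusted over the list alone), above the other genes (camera adjusted p = 4.82e-18), which held with an estimated correlation (1.45e-05). JOX2, an enzyme that inactivates jasmonate, rose by 5.11 ± 0.45 (adjusted p = 3.61e-21), and the biosynthesis genes AOC1, LOX3, AOS and LOX2 by 3.64 ± 0.48, 3.59 ± 0.43, 2.35 ± 0.17 and 2.17 ± 0.11. The storage protein gene VSP1 rose by 3.35 ± 0.48. CYP94B3, which oxidises the active hormone, had 2 fragments in the 8 unwounded and 85 in the 8 wounded libraries, a ratio of 104 with a 95% counting interval of 27.9 to 873. MYC2 was not called without rns2 wounded replicate 1 (adjusted p = 0.0995). JAZ9, 0.90 ± 0.37, did not pass (adjusted p = 0.0559). In the RNase T2 list only RNS1 was measured, and it passed (adjusted p = 0.00616), with 51 fragments in wounded and 2 in unwounded libraries, a ratio of 62.4 with a 95% counting interval of 16.4 to 529. It was not called without rns1 wounded replicate 2 (adjusted p = 0.9997). That library holds the only RNS1 fragment of wounded rns1 leaves, and unwounded WT leaves hold 0. Without that library the fold averaged over genotypes cannot be estimated, so this p-value says nothing about RNS1 in WT leaves. Of the tissue lists, guard cell (TGG1 0.37 ± 0.12 and TGG2 0.99 ± 0.15, 2 of 2 rose; 0.0326) and mesophyll photosynthesis (7 of 15 rose and 1 fell; 0.00659) lay above the other genes, with adjusted p = 0.150 and adjusted p = 0.194 with an estimated correlation. In the second, GAPB rose by 0.81 ± 0.12 and RCA by 0.67 ± 0.08 and LHCB1.2 fell, -0.39 ± 0.10, but its median, 0.26, turned to -0.18 with library totals. TGG1, RBCS1A, RBCS3B, LHCB3 and GAPA turned to -0.07, -0.03, -0.04, -0.18 and -0.08 there, and TGG1 was not called without any 1 of rns2 unwounded replicate 1 or 2, rns2 wounded replicate 1 or 2 (adjusted p = 0.101 to 0.241), RBCS3B not without rns2 unwounded replicate 1 (adjusted p = 0.0721) or rns2 wounded replicate 1 (adjusted p = 0.117), LHCB3 not without any 1 of rns2 unwounded replicate 1 or 2, rns2 wounded replicate 1 or 2 (adjusted p = 0.189 to 0.320) and GAPA not without any 1 of rns1 wounded replicate 1, rns2 unwounded replicate 1 or 2, rns2 wounded replicate 1 or 2 (adjusted p = 0.112 to 0.277). 2 of 4 epidermis genes rose (3 adjusted over the list alone), CER1 by 0.69 ± 0.24 and FDH by 0.55 ± 0.22 (0.163). CER1 was not called without rns2 unwounded replicate 1 (adjusted p = 0.177) or rns2 wounded replicate 2 (adjusted p = 0.415), and FDH not without any 1 of WT unwounded replicate 1 or 3, WT wounded replicate 1, rns1 unwounded replicate 2, rns1 wounded replicate 1, rns2 unwounded replicate 1 or 2, rns2 wounded replicate 1 or 2 (adjusted p = 0.0518 to 0.237) nor with the replicate block (0.50, adjusted p = 0.0775). By edgeR, 0 of 2 phloem companion cell genes passed (SUC2 0.49 ± 0.41 and SULTR2;1 0.88 ± 0.44; 0.310). The phosphate starvation (40 wounded and 95 unwounded fragments), salicylate and pathogen (32 and 34) and clock lists (146 and 235; PRR7 0.86 ± 0.41, adjusted p = 0.104) had too few measured genes to test.

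**Figure D5:**
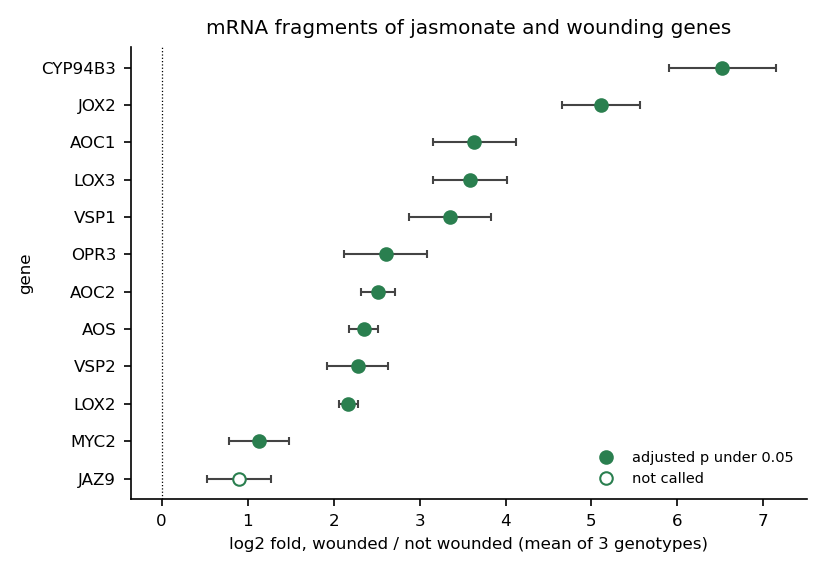
Log2 fold ± SE after wounding (horizontal axis), averaged over the 3 genotypes, of mRNA fragments of the 12 measured jasmonate and wounding genes (vertical axis). All lie to the right of 0 and 11 passed the test.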

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

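The tests of splits, except the one that swaps genotype within a time, all tests of the miRNA share and the tests of chloroplast rRNA and mRNA were chosen only after the result was seen. The ratio to chloroplast rRNA in pattern 1 was added when its value was known, and the splits that swap wounding within a genotype were set aside when their count was known. The effect of wounding differed between rns1 and WT for 49 features, the effect of wounding between rns2 and WT for 163 and the effect of added tRNA between rns2 and WT extract for 172, each by the interaction test in edgeR.

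Other splits of the same libraries show how far chance can be excluded. With 10 splits of 6 libraries the splits are too few for a share under 0.05: 1 of 10 splits gave as many features for WT wounding (264, highest other 0), rns1 wounding (292, highest other 0), rns1 against WT before wounding (22, highest other 11) and rns1 against WT after it (58, highest other 0). The split with 11 parts 1 of the 3 pairs of the same number, and the 3 other splits that part all 3 pairs, as the real one does, gave 0. For rns1 minus WT wounding, 1 of 100 splits that swap genotype within a time reached the 49 features (highest other 32), but neither this fit nor these splits keep the pairs. Those 100 splits therefore cannot decide for paired libraries. With the replicate block and genotype swapped only within pairs, 1 of 32 splits, the least possible, reached the 86 features (highest other 37, from swapping all 3 wounded pairs). Swapping all 3 wounded pairs turns a genotype difference shared by both times into an interaction. Mixed swaps add such a difference to the spread, which can lower their counts. These 32 splits, chosen after the result was seen, therefore argue against chance only for genotype differences of any kind, under the replicate block. They cannot decide the interaction alone. When wounding labels were swapped within a genotype, 8 of 100 splits reached 49 (highest other 279). Inverting wounding in 1 genotype turns the wounding effect into an interaction, which points to structure of the samples, so these splits cannot tell. Of 100 splits for miRNA 1 reached the real count (36, highest other 28), and 1 of 100 for mRNA (1058, highest other 127). Neither these fits nor these splits keep the pairs of WT and rns1, so they argue against chance only for libraries taken as unpaired.

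Pattern 1 is the low miRNA share of unwounded rns2 leaves, 2.02 ± 0.0640% against 24.6 ± 2.03% in WT. The tables argue against breakdown of all long RNA alike: per miRNA tag nuclear rRNA fragments were 57.5-fold and mRNA fragments 2.65-fold higher in rns2, a ratio of 21.7, and chloroplast rRNA fragments only 2.54-fold, a ratio of 22.6. A candidate explanation is that rRNA and tRNA fragments take the place of miRNA in the tag total, since among the other tags the miRNA share in rns2 was still 0.769 of that in WT. Loss of RNS2, the biological difference in the design, stays open and was not tested apart from other differences between the libraries of the 2 genotypes.

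Pattern 2 is the rise of chloroplast tRNA features in rns2 after wounding. Rarity before wounding is argued against, since 70 of the 84 features that rose had a mean of 10 tags or more in unwounded rns2 libraries. More chloroplast RNA of every kind stays open, because the 2 other kinds of RNA point different ways: the chloroplast part of mRNA fragments was 4.45-fold higher, as was that of tRNA tags, and that of rRNA tags only 1.89-fold. A response of chloroplast tRNA alone is therefore not shown. Chloroplast tRNA rose in the other genotypes too, from 2.55% to 3.38% of tags per unwounded library to 6.52% to 7.45% per wounded one in WT. In rns1 the shares were 2.52% to 3.08% and 8.61% to 11.1%. These values argue against loss of RNS2 as needed for the rise. Whether that loss changes its size stays open, since folds of single features were both higher and lower than in WT. It was not tested against a second mutant line. Wounding stays open as well and cannot be told from elapsed time.

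Pattern 3 is the lower share of 5′ fragments that end at positions 15 to 22 in rns2 extract, 41.4 ± 5.38% against 78.1 ± 4.78% in WT extract. Nuclear Ala tags alone are argued against, since without them the difference was 32.1 points. Tags shared between families are argued against as well: with only tags of 1 family the difference was 36.1 points. In unwounded leaves the share was 34.5 ± 1.39% in rns2 and 39.0 ± 6.29% in WT, and in wounded leaves 34.3 ± 2.97% and 48.0 ± 0.841% with no overlap. These leaf shares are with all tags, and the wounded WT share was lower without nuclear Ala, as given above. The test without nuclear Ala covered the extract alone, so the leaf difference may rest on those tags. Ends were counted only in tags of 15 nt or more. With shorter tags counted, tags of 14 nt were 17.5 ± 2.70% of matched tags in rns2 extract. In WT extract they were 5.21 ± 0.253%, both from all kinds of RNA. Whether 5′ fragments under 15 nt would change the difference between the extracts was not tested. Loss of RNS2 and other differences between the extracts stay open with 2 libraries per group, and cleavage by RNS2 itself was not tested.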

How the results depend on the processing

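Families by amino acid, tags of 13 to 60 nt or 15 to 40 nt, fits without rns2 leaf libraries the block in the list test and the block with other rns2 numbers were chosen only after the results were seen. Of 435 single results 316 kept direction and call under every alternative and left-out library run, 72 lost their call and 32 gained one under at least 1, and 29 turned direction. Depth limits fragments of single mRNAs such as RNS1 and RNS2. Whether replicate numbers pair rns2 leaf or extract libraries could not be shown. The check required 3 pairs, and the deviations of 2 libraries from their mean mirror each other. With the numbers of the titles the correlations were 0.23 for rns2 wounding, -0.35 to 0.03 and -0.33 to -0.28 for rns2 against WT in leaves and -0.02, 0.41, 0.15 and 0.33 in extract. The rns2 leaf numbers are in doubt: titles give 1 and 2, the deposited files 2 and 3. Read as 2 and 3, their correlations with WT were 0.346 to 0.356 before and -0.0911 to 0.329 after wounding, and with rns1 0.277 to 0.469 and 0.201 to 0.307. A block with those numbers gave 69, 132 and 120 features for rns1 against WT before wounding, after it, and for the interaction, and changed no call of a named feature that the block by titles had not changed. The replicate block by titles gave 52, 93 and 86 features for rns1 against WT before wounding, after it, and for the interaction with wounding. It gave a call to Leu(CAA) 5′ long in the added-tRNA interaction (0.99) and to chloroplast fMet(CAT) 5′ short in WT extract (0.62), and changed no other call of a named feature than these and those in the report. In the list test it ended the calls of Ser in WT extract with added tRNA (adjusted p = 0.0683) and 3′-half in rns2 extract with added tRNA (0.0789), and gave calls to 5′-half (0.0274) and Ser (0.0495) in rns2 against WT with added tRNA.

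For rns1 against WT before wounding, after it and the interaction, library totals gave 0 (by edgeR; 66 at unadjusted p under 0.05 with TMM, and 43 by DESeq2), 58 and 16, miRNA scaling 4, 146 and 121, DESeq2 43, 91 and 88, and the compared groups alone 0, 30 and 23. The first gave 4 without the filter and 0 with 18 to 60 nt. Library totals gave 62 miRNA families and 1761 genes, and miRNA scaling 20 families. The cause was not tested. Amino acid families have fewer features by construction, and gave 157 in WT wounding, 185 in rns1 wounding, 11 in rns1 against WT before wounding, 135 and 118 in rns2 against WT before and after it, 27 and 103 in the rns1 and rns2 interactions, and in extract 165, 203, 159, 175 and 106. With the ratio to miRNA the differences in tRNA share turned to 0.0316 for rns1 minus WT before wounding, 19.8 for rns2 minus WT after it, 9.08 in extract and 69.7 with added tRNA, and with 18 to 60 nt the last turned to 1.47 points. With an estimated correlation 1 list was called in WT wounding, 3 in rns2 wounding, 2 in rns2 against WT before wounding, 1 in mRNA and 0 in the other 12 results (camera; fry called 0 to 31 of them).

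With 18 to 60 nt, tags of 15 to 17 nt are removed by construction. Ala(CGC) 5′ short turned to -0.17 in WT wounding, 2.52 in rns2 against WT with tRNA and 3.47 in the added-tRNA interaction, Ala(AGC) to 0.88 and 1.83 in the last 2, chloroplast fMet(CAT) to 1.99 in extract, 1.29 with tRNA and -0.71 in the interaction, Pro(TGG) to 0.0837 in extract, 1.80 with tRNA and 1.80 in WT with tRNA added, Thr(TGT) to 0.00182 and Trp(CCA) to 0.0777 in extract, and in rns2 extract Glu(CTC) to 1.70 and Arg(CCG) internal to 0.62. Library totals turned, in rns2 against WT after wounding, Asp(GTC), Gly(TCC), Glu(TTC) and His(GTG) 5′-half to -0.43, -0.38, -0.55 and -1.16 and Ala(CGC) and Gly(TCC) 5′ short to -1.76 and -0.0189, and TGG1, RBCS1A, RBCS3B, LHCB3 and GAPA to -0.0717, -0.0251, -0.0360, -0.18 and -0.0799. miRNA scaling turned Glu(CTC) 5′ short to 0.75 and Gly(TCC) 5′-half to 0.77 and 0.80 in extract, and miR398 to 0.0117. The cause was not tested.

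Leaving out 1 library gave these ranges: for wounding 238 to 261 in WT, 276 to 297 in rns1 and 69 to 77 in rns2, for rns1 against WT 0 to 23 before and 13 to 58 after wounding, for rns2 against WT 198 to 219 and 148 to 181, for the interactions 8 to 59 (rns1) and 148 to 167 (rns2), in extract 166 to 259, 289 to 310, 224 to 248, 226 to 327 and 137 to 211, and 29 to 41 miRNA families and 875 to 1155 genes. The 0 stands for the libraries named in the report (edgeR). Where a group is left with 1 library it is assumed to vary like the other groups. The difference in tRNA share of rns1 and WT before wounding ranged from -0.781 to 0.314 points and turned direction without rns1 unwounded replicate 1 (0.0398) or 3 (0.0806) or WT unwounded replicate 2 (0.314) or 3 (0.0182). No other share difference turned.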

Other observations

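The values of this part other than the shares of 24-nt tags were chosen only after the results were seen, and no share could pass an exact permutation test at 0.05. Mitochondrial tRNA fragments were nearly all 5′ short fragments of His: these made up 0.0615 ± 0.0532% of matched tags in unwounded and 1.27 ± 0.242% in wounded WT leaves (n = 3 each), 0.0728 ± 0.0327% and 1.22 ± 0.0912% in rns1 and 0.00463 ± 0.00129% and 0.112 ± 0.00327% in rns2 (n = 2 each). In extract they made up 1.31 ± 0.167% in WT and 0.129 ± 0.0441% in rns2.

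Tags of 24 nt, the length of short interfering RNA at repeats, were 28.7 ± 0.390% of matched tags in unwounded and 16.0 ± 2.65% in wounded WT leaves, 29.6 ± 0.786% and 12.4 ± 0.962% in rns1 and 5.78 ± 0.0574% and 5.09 ± 0.0206% in rns2. Those from neither tRNA nor rRNA were 27.8 ± 0.496% and 15.3 ± 2.51% in WT and 2.53 ± 0.0175% and 1.95 ± 0.178% of matched tags in rns2. Taken as a percentage of the tags from neither tRNA nor rRNA they were much closer, 36.4 ± 0.767% and 34.5 ± 2.05% in WT, 37.8 ± 0.722% and 33.6 ± 1.24% in rns1 and 31.01 ± 0.00808% and 25.6 ± 1.32% in rns2, so most of the difference lies in the tRNA and rRNA fragments of the total. Nuclear 25S rRNA fragments made up 18.7 ± 0.497% of tags in rns2 extract and 3.39 ± 0.384% in WT extract (n = 2 each). Chloroplast 23S fragments were 1.83 ± 0.285% and 1.32 ± 0.413%.

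Tags over 60 nt, outside every comparison, made up 0.699 ± 0.173% of reads in WT extract, 0.583 ± 0.104% with added tRNA, 0.873 ± 0.0697% in rns2 extract and 0.734 ± 0.0503% with added tRNA (n = 2 each). Tags of 13 to 14 nt made up 26.1% and 21.5% of reads in rns2 extract replicates 1 and 2, and tags under 13 nt 24.4% and 21.7%, the latter against 7.27% and 7.67% in WT extract. Among miRNA and mRNA comparisons without the rns2 leaf libraries, 7 miRNA families rose and 34 fell of 104, and 600 genes rose and 558 fell of 3219.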
